A study of Arabidopsis thaliana with 12 samples.

How the data were processed

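The samples were 12 whole-root RNA preparations of Arabidopsis thaliana, 3 each of the wild type Wassilewskija (ws2) and the mutants akt1, cngc1 and cngc4, grouped by the genotype and replicate number in the labels. Per the labels' protocols, RNA was extracted with TRIzol, labelled with biotin and hybridised to an array of 22810 probe sets, with 20 to 40 plants pooled per sample. The deposited values are 1 intensity (signal) per probe set and array on a linear scale. The software and genome annotation behind them are not given in the sources used here. The mean after trimming 2% of the probe sets at each end was the same on every deposited array to 3 significant digits, so the intensities had been scaled before deposit. The table used here holds no detection calls, so low signal was judged from the values.

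The values were analysed as log2(signal + 16) with no further normalization. The 64 control probe sets were left out, and a probe set was kept if it lay above the 40th percentile of its array on at least 3 arrays, which left 14745. Limma 3.58.1 in R 4.3.3 fitted 4 group means to all 12 arrays, with eBayes and a mean-variance trend; tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The 6 comparisons were each mutant against ws2 and the mutants against each other, with an F test over the 3 mutants. With 3 arrays against 3 an exact permutation test cannot go below p = 0.10, so none was used for single genes. Figures were drawn with matplotlib 3.10.9.

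The method was tested on simulated data for cngc4 against ws2, with 200 of 14745 probe sets changed in each of 10 runs. It recovered 20.6% of those changed by 0.5 on the log2 scale, 83.8% at 1 and 99.4% at 2, and 4.90% of its calls were false. A list shifted by 0.5 was called by camera in 10 of 10 runs, and an unshifted one in 1. Every simulated gene was drawn independently, while the real lists have estimated correlations of up to 0.63 between genes. The runs therefore do not show how often false calls of lists or genes arise when genes are correlated. Recovery under Benjamini-Hochberg also depends on the share of probe sets changed. In the real data 1340 were called in cngc4, 1 in cngc1 and 0 in akt1, so the recovery rates do not carry over to these comparisons as they stand.

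Gene names came from the annotation table of the array: 13513 probe sets list 1 gene, 503 list several and were not named, and 8794 are unnamed here. Symbols were updated through the gene table of assembly TAIR10.1, in which 13436 of the 13513 were found; it was used for names and gene order only. Many genes are known here by locus number alone. The array's own build is not given in the sources used here, so no coordinates are printed.

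Before the data were examined, the design, the alternatives, 26 gene lists with 502 entries and the rule for named genes were fixed. The rule names, per mutant, up to 10 genes with the largest change in each direction among those that pass, name 1 gene and have all 3 mutant arrays beyond all 3 wild-type arrays; where fewer than 5 pass, the 5 of smallest p in each direction; per list up to 4 members; and per comparison of mutants up to 5 in each direction. The targeted genes and the potassium and cyclic nucleotide-gated channel families, also in the rule, were not analysed here. Because only 30 of the fixed loci were tested, 28 further lists were built from the symbols in the annotation table, chosen after the probe names were seen and before any comparison of genotypes was computed. Each gene was represented by its probe set of highest mean signal. Lists with at least 5 tested genes, 27 in all and each from the added ones, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Camera compares a list with the other genes, and fry asks whether the genes of a list move one way on balance.

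Whether replicate numbers pair the samples was checked by correlating the arrays' deviations from their group means: of 18 pairs with the same number in different groups, 3 exceeded 0.1, with a range from -0.17 to 0.27, so the numbers were not taken as pairs. No 2 arrays held identical values. Shifts of the median log2 signal between genotypes were at most 0.05 in size. Alternatives were quantile normalization, median centring, no offset or an offset of 64, no filter or a 60th-percentile filter, eBayes without a trend or robust, array weights, the replicate number as a block, the repeat mark as a covariate, fits of only the 2 groups compared, an unadjusted p under 0.05 with a 2-fold change, each array left out, and for neighbours windows of 50 and 200 genes on each side in place of 100. Added after the data were seen were the fits without repeat-marked arrays and within marked and unmarked arrays.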

Results

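Whole-root transcript levels were measured in Arabidopsis thaliana of 4 genotypes on 12 single-colour GeneChips, 3 per genotype. The wild type, called ws2 here, is the accession Wassilewskija. The mutants are akt1, cngc1 and cngc4, each named for the channel it lacks: AKT1 is an inward potassium channel of root cells, and CNGC1 and CNGC4 are cyclic nucleotide-gated cation channels. The question of the series is how the transcript profile differs in each. The labels give the Wassilewskija background for akt1 and not for the cngc lines, so a difference of cngc1 or cngc4 from ws2 may include a difference between accessions. Each sample pooled 20 to 40 plants, and the labels do not say whether replicates came from separate growths, so p-values measure the spread between these samples only. Values are the deposited signals, in arbitrary units on a linear scale, and fold changes are differences of log2(signal + 16), which understates the change of weak probe sets. Of 22810 probe sets, 14745 were tested, and 8132 of these name 1 gene in the annotation used here. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.16.

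The 12 arrays had the same scale, while RNA quality readings differed between some genotypes. The median signal lay between 43.3 and 48.5 on every array. The ratio of 3-prime to 5-prime signal of the actin control ran from 1.42 to 2.06 over all arrays, and from 1.64 to 1.94 in cngc4. In cngc1 it ran from 1.42 to 1.54, below every akt1 and cngc4 array. Comparisons of cngc1 with these mutants may thus include a difference in RNA quality. The GAPDH ratio did not show this: it was 1.12 to 1.24 in cngc1, 1.12 to 1.19 in akt1 and 1.06 to 1.25 in cngc4. In ws2 the GAPDH ratio ran from 1.03 to 1.09, below every akt1 and cngc1 array. Comparisons of akt1 and cngc1 with ws2 may therefore also include a difference in RNA quality. For the GAPDH control, cngc4 replicate 2 had the highest ratio of all arrays, 1.25. The cngc1 replicate 3 array had the highest background (143) and noise (12.9), with 1251 outlier cells, and its mean correlation with its own group was 0.954, the lowest of the 12. The cngc4 arrays each correlated best with another cngc4 array. AKT1, CNGC1 and CNGC4 were not analysed here, so the genotype labels were not checked against the targeted genes.

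In cngc4 roots, GAT1_2.1, ASPGB1, MCCB, MCCA and MGL were among the named genes with the largest increases over ws2. GAT1_2.1, a glutamine amidotransferase-like protein, rose from a signal of 128 ± 11.5 in ws2 to 862 ± 241 in cngc4 (SD, n = 3 each), a log2 fold change of 2.57 with limma adjusted p = 0.0148. ASPGB1, an asparaginase, rose from 127 ± 18.9 to 615 ± 198 (adjusted p = 4.91e-04). Both subunits of methylcrotonyl-CoA carboxylase, an enzyme of leucine breakdown, rose: MCCB by 1.94 and MCCA by 1.70 on the log2 scale. MGL, methionine gamma-lyase, rose by 1.75, and the ubiquitin ligase gene ATL8 by 1.79. In the other direction, the beta-expansin EXPB2, which loosens cell walls, fell from a mean of 508 to 130, a log2 fold change of -1.85 with a standard error of 0.27 and adjusted p = 0.00105.

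The other genes with the largest changes in cngc4 are known here by locus number only. AT5G66180, AT2G15960, AT1G19530 and AT1G19960 rose by between 1.75 and 1.87 on the log2 scale. AT4G11190, AT1G20070, AT4G25250, AT5G14650 and AT5G04120 had log2 fold changes between -1.85 and -1.75. AT1G78990, AT1G73600, AT2G38600 and AT1G09750 had log2 fold changes between -1.58 and -1.43. For each of these genes the 3 cngc4 arrays all lay on one side of the 3 ws2 arrays. AT5G66180 and AT1G19960 in ws2, and AT1G78990 and AT5G04120 in cngc4, had mean signals below the 40th percentile of each array, so the sizes of their folds are not exact.

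Limma called 1340 probe sets between cngc4 and ws2, 692 higher and 648 lower in cngc4, and 680 of them name 1 gene. With each array centred on its median the count was 1285, of which 804 were higher and 481 lower, so the share of higher calls moved from 51.6% to 62.6%. At least a 2-fold change was seen for 154 of the higher and 85 of the lower probe sets. The 3 arrays of each genotype did not overlap for 30.9% of the probe sets tested, where chance gives 10%. The count fell to 321 without cngc4 replicate 2, 670 without ws2 replicate 1, 589 without ws2 replicate 2 and 886 without ws2 replicate 3. The titles mark ws2 replicates 2 and 3 and cngc4 replicate 1 as repeats, without saying of what: with that mark as a covariate 714 probe sets were called. Within unmarked arrays alone (1 ws2 and 2 cngc4) 17 were called, and within marked arrays (2 ws2 and 1 cngc4) 5 were called, in 1 fit that assumes a lone array to vary like the others. All 1340 probe sets kept their direction in both, with median log2 fold changes of 0.70 and -0.70 among unmarked and 0.67 and -0.64 among marked arrays; these are the arrays from which the 1340 were chosen.

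**Figure D1:**
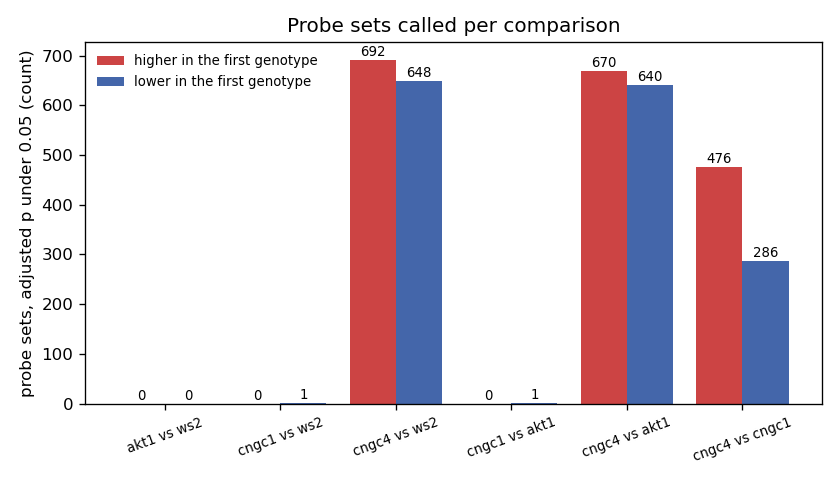
Number of probe sets past an adjusted p of 0.05 in each of the 6 comparisons, as bars for higher (red) and lower (blue) in the first-named genotype. The cngc4 comparisons reach 1340, 1310 and 762 probe sets in all, against 0 and 1 for akt1 and cngc1 over ws2.

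Some genes of photosynthesis and of the organelle genomes rose in cngc4, in lists that, like all lists tested as groups here, were chosen after the probe names were seen. Of 62 plastid-encoded genes tested, 8 rose and 54 did not pass; 59 had a positive log2 fold change, with a median of 0.46. Examples are psbF of photosystem II (log2 fold change 0.78), the ATP synthase subunit atpA (0.77) and the ribosomal protein rps4 (0.72). Of 19 nuclear photosynthesis genes 5 rose, among them the antenna protein LHCB4.1 (1.34) and the chlorophyll synthesis enzyme CHLM (0.64), and 14 did not pass; the median was 0.47. Photosynthesis genes are also markers of shoot tissue, and this shift stands beside the other gene groups of cngc4 given here. Of 11 mitochondria-encoded genes 2 rose, cox1 (0.55) and nad4L (0.54). Camera with a preset correlation called these 3 lists higher, with adjusted p of 1.04e-11, 1.57e-05 and 0.021. With an estimated correlation none of these calls held, with adjusted p = 0.337, adjusted p = 0.252 and adjusted p = 0.366 in the same order, and the mitochondrial call was lost in 5 of 26 alternative settings. By fry the nuclear list passed (adjusted p = 0.0202), and the plastid (adjusted p = 0.0578) and mitochondrial (adjusted p = 0.0767) lists did not.

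Some cell wall genes fell in cngc4, and most of those tested did not pass. Of 21 secondary wall and xylan genes 6 fell, all of the TBL family, of which several members acetylate wall polymers; TBL36 (-0.78) and TBL19 (-0.71) are examples, and 15 did not pass. Of 13 expansins 4 fell, EXPB2 among them, while the expansin-like EXLB1 rose by 1.43. Of 9 xyloglucan endotransglucosylases 3 fell, with XTH20 at -0.83, and EXGT-A3 rose by 0.81. Of 9 endoglucanases of family GH9 only GH9B13 passed (-1.07). Camera called all 4 lists lower, with adjusted p of 0.00109, 0.021, 0.021 and 0.0365. None of the 4 calls held with an estimated correlation, which gave adjusted p = 0.252 for the first 3 and adjusted p = 0.365 for GH9. By fry the first 3 passed, with adjusted p of 0.0121, 0.0234 and 0.0202, and GH9 did not (adjusted p = 0.0578). The GH9 call was lost in 8 of 27 alternative settings and the xyloglucan endotransglucosylase call in 4, among them without a filter (adjusted p = 0.103) and without cngc4 replicate 1 (adjusted p = 0.105).

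A few glutathione transferases and serine carboxypeptidases fell in cngc4. Of 12 glutathione transferases, which conjugate glutathione to reactive compounds, GSTU28 (-1.12) and GSTU20 (-1.04) fell, GSTU16 rose by 0.79 and 9 did not pass (camera adjusted p = 0.00484). Of 17 serine carboxypeptidases 4 fell, with scpl40 at -0.87 and scpl48 at -0.73 (camera adjusted p = 0.00185). Of 19 mitosis and DNA replication genes only the Aurora kinase AUR1 passed (-0.45), and the list was called lower (camera adjusted p = 0.0269). Of 18 defence signalling genes only the zinc finger regulator STZ passed (0.99), and the list was called higher (camera adjusted p = 0.0492). With an estimated correlation these became adjusted p = 0.252, adjusted p = 0.252, adjusted p = 0.366 and adjusted p = 0.365. By fry the glutathione transferases and serine carboxypeptidases passed (adjusted p = 0.00935 for each). The mitosis (fry adjusted p = 0.0578) and defence signalling (fry adjusted p = 0.0709) lists did not. The defence signalling call was lost in 14 of 27 alternative settings and the mitosis call in 8. Without cngc4 replicate 3, 7 of the 11 lists called in cngc4 were left.

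**Figure D2:**
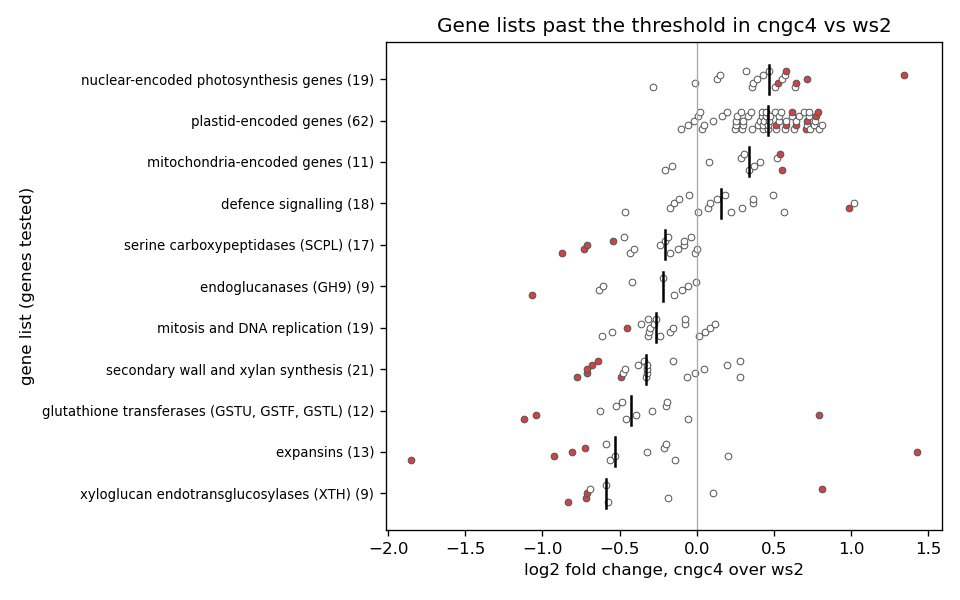
Log2 fold change of cngc4 over ws2 for each gene (points, filled red where the adjusted p was under 0.05) of the 11 lists that camera called with a preset correlation, with the list median as a black bar. Medians run from -0.59 for xyloglucan endotransglucosylases to 0.47 for nuclear photosynthesis genes, and most single genes did not pass.

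The remaining 16 lists did not pass in cngc4, the lowest camera adjusted p being 0.0962 for the RALF-like peptides. Members that passed were UGT73B1 (0.74), UGT87A2 (0.67) and UGT72E3 (-0.87) among 24 glycosyltransferases, SWEET2 (0.54) and SWEET13 (-0.82) among 9 SWEET sugar transporters, and ATG8B (0.74) among 9 autophagy ATG8 genes. Others were the auxin-conjugating enzyme gene GH3.17 (-1.10), RALFL24 (-0.74), the tubulin TUB1 (-0.74), DI19 (0.63), bHLH121 (0.72) and LCR68 (-0.50). No member passed among 6 CYP71B cytochromes, 8 beta-glucosidases, 6 ER body and jacalin-related genes, 6 calmodulin-like proteins, 7 U-box ligases, 7 MADS-box genes and 9 tetraspanins.

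**Figure D3:**
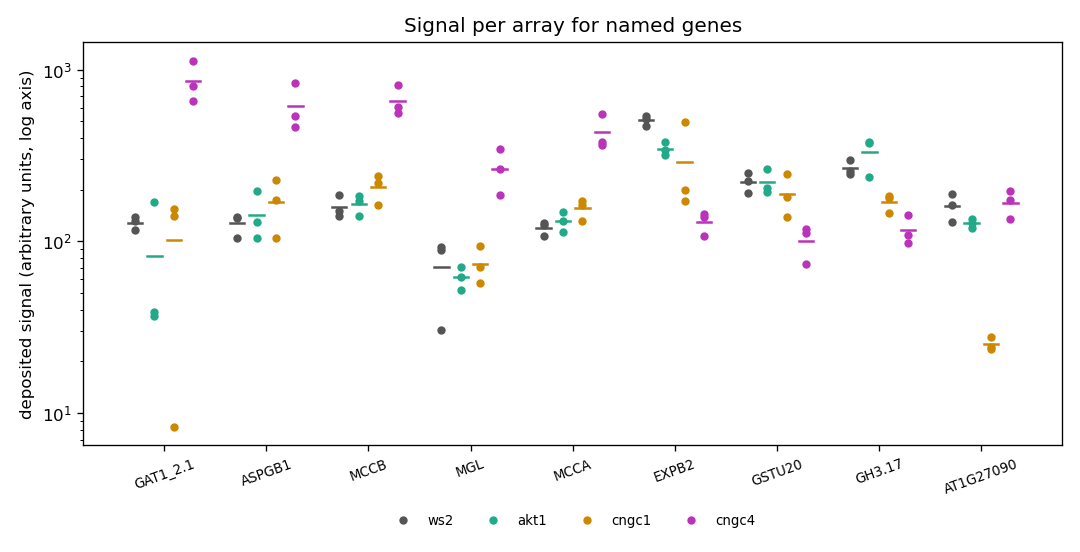
Deposited signal (log axis, arbitrary units) of 9 named genes on each of the 12 arrays, as points coloured by genotype with the group mean as a short line. GAT1_2.1 reads 862 on average in cngc4 against 128 in ws2, and AT1G27090 reads 25.2 in cngc1 against 160 in ws2.

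In cngc1 roots, 1 gene fell and no other probe set passed. AT1G27090 dropped from 160 ± 29.1 in ws2 to 25.2 ± 2.29 in cngc1 (SD, n = 3 each), a log2 fold change of -2.08 with limma adjusted p = 6.22e-06. Its signal was at most 27.8 in cngc1, below the 40th percentile of each cngc1 array, so the size of the drop is not exact; the log2 fold change ran from -2.65 to -1.32 over the alternative settings. Its signal was 127 ± 7.46 in akt1 and 168 ± 31.3 in cngc4. Among probe sets that name 1 gene, the one with the next smallest p, AT3G05950, read 557.5 ± 46.4 in ws2 and 1336 ± 307 in cngc1 and did not pass (adjusted p = 0.169). Further genes that did not pass were, with positive log2 fold changes, AT5G66180 (1.48, from a low signal in ws2), AT1G49570 (1.17), AT4G38410 (1.04) and AT2G35750 (0.54), and with negative ones AT5G66390 (-0.82), AT4G28085 (-0.80), AT3G49070 (-0.62) and AT1G56320 (-0.59).

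Camera with a preset correlation called 2 lists lower in cngc1, in which no single gene passed. Of 9 SWEET sugar transporters 8 had a negative log2 fold change (adjusted p = 0.00655), with SWEET16 at -0.48. Of 12 glutathione transferases 10 had a negative one (adjusted p = 0.012), with GSTU28 at -0.48. Of 27 alternative settings, the SWEET call was lost in 6 and the glutathione transferase call in 5. Both calls were lost with an estimated correlation (adjusted p = 0.36 for each). Both were also lost with the repeat mark as a covariate (SWEET adjusted p = 0.0506, glutathione transferases adjusted p = 0.0601) and without the marked arrays (adjusted p = 0.285 and adjusted p = 0.0513). An unadjusted p under 0.05 was reached by 1080 probe sets, where chance gives 737. The count of called probe sets was 3 without akt1 replicate 1, 2 without cngc1 replicate 2 and 1 without cngc1 replicate 3; without cngc1 replicate 1, 0 lists were called.

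In akt1 roots no gene passed the test against ws2. Among probe sets that name 1 gene, those with the smallest p were, with positive log2 fold changes, AT5G66180 (1.15), AT3G05950 (0.86), AT2G31490 (0.63), AT2G19180 (0.59) and AT2G23120 (0.53), and with negative ones AT1G33612 (-0.92), AT3G27950 (-0.85), AT4G04630 (-0.84), the plastid gene psbZ (-0.70) and AT1G71710 (-0.61). AT5G66180 and AT2G19180 in ws2 and AT4G04630 in akt1 had mean signals below the 40th percentile of each array, so the sizes of their changes are not exact. All 10 genes had an adjusted p of 0.957; the smallest over all probe sets was 0.375, for 1 that is unnamed here. Limma called 0 probe sets; 746 had an unadjusted p under 0.05, where chance gives 737. Without akt1 replicate 1 the count was 1.

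Camera called 3 lists in akt1 with a preset correlation. Of 62 plastid-encoded genes 58 had a negative log2 fold change, with a median of -0.29 (adjusted p = 1.04e-11). Of the 19 nuclear photosynthesis genes, the shoot tissue markers, 14 had a negative one, with a median of -0.21, and that list did not pass (adjusted p = 0.188). All 9 autophagy ATG8 genes had a positive one, with a median of 0.21 (adjusted p = 4.61e-04), and so did 6 of 7 RALF-like peptides, with a median of 0.30 (adjusted p = 0.00152). No single member passed over all probe sets. With an estimated correlation each list had an adjusted p = 0.519. With the repeat mark as a covariate the ATG8 call (adjusted p = 0.30) and the RALF call (adjusted p = 0.0601) were lost. Leaving out akt1 replicate 2 or ws2 replicate 2 left 1 list called, and 5 were called without ws2 replicate 3.

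The 26 gene lists fixed before the data were examined could be followed for few genes, because 30 of their 496 distinct loci were tested here. Of these 30, 2 passed in cngc4 over all probe sets, STZ (0.99) of the touch and calcium sensors and AUR1 (-0.45) of the meristem and cell cycle list, and none passed in cngc1 or akt1. Adjusted over the list alone, 7 passed in cngc4: STZ, AUR1, CYP71B6 (0.52), GSTU25 (-0.63) and the shoot photosynthesis markers RCA (0.63), PRK (0.51) and SBPASE (0.36). Adjusted over the list alone, GSTU25 (-0.46) and ATHSP22.0 (-0.71) passed in cngc1 and none in akt1; the lists of these 2 genes have 1 tested member each, so no adjustment was made there. Adjusted over all 30 genes together, STZ and AUR1 alone passed in cngc4 and none in cngc1.

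Members that passed in no mutant are given as cngc4 values. The glutamate receptor-like channels GLR1.4 (-0.20) and GLR3.3 (0.15) were among 4 tested, none of which passed. Defence genes read 0.13 for GRX480, 0.08 for WRKY53 and 0.51 for PDF1.2b. Stress and nutrient genes read -0.31 for COR47, 0.32 for LTI30, 0.68 for PDC2 and -0.27 for ZIP9. Cell type markers read -0.32 for EXPA18 and -0.21 for EXPA7 (root hairs), -0.32 for GUT2 (xylem) and 0.11 for SWEET11 (phloem). Potassium channels, potassium transporters and cyclic nucleotide-gated channels were not analysed here.

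Set against the other mutants, cngc4 differed in many of the genes that differed from ws2. These comparisons share the cngc4 arrays, which raises that overlap by an amount that was not estimated. Against akt1, GAT1_2.1 was 10.6-fold higher, and AT3G05150 (log2 fold change 2.17), ASPGB1 (1.98), MCCB (1.88) and MGL (1.82) came next. AT4G11190 (-1.92), AT4G25250 (-1.48), AT3G25790 (-1.43), AT5G04120 (-1.41) and AT1G09750 (-1.41) were lowest. The signal of AT5G04120 in cngc4 was low, so the size of its change is not exact. Against cngc1, GAT1_2.1 was 9.87-fold higher, and AT1G33055 (2.54), AT2G15960 (2.33) and AT3G05150 (2.02) were also among the highest, as was AT1G27090 (2.14, or 1.37 to 2.72 over the alternative settings, its signal in cngc1 being low), with AT2G38600 (-1.52), AT1G73600 (-1.47), AT1G09750 (-1.40), AT5G01740 (-1.35) and AT3G19430 (-1.26) lowest. Between cngc1 and akt1, AT1G27090 alone passed (-1.80, with the same low signal in cngc1).

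Some photosynthesis genes and xyloglucan endotransglucosylases differed between cngc4 and the other mutants. Of 62 plastid-encoded genes 32 were higher in cngc4 than in akt1, with a median of 0.73, and 6 were higher than in cngc1, with a median of 0.45. Of 19 nuclear photosynthesis genes 10 were higher than in akt1 and 3 higher than in cngc1. Of 9 xyloglucan endotransglucosylases 4 were lower than in akt1 and 3 lower than in cngc1. Camera with a preset correlation called 10 lists in each of these comparisons and 3 between cngc1 and akt1. With an estimated correlation 0 were called, the smallest being adjusted p = 0.206 against akt1, adjusted p = 0.256 against cngc1 and adjusted p = 0.534 between cngc1 and akt1.

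Limma called 1310 probe sets between cngc4 and akt1, 670 higher and 640 lower, and 762 between cngc4 and cngc1, 476 higher and 286 lower. With arrays centred on their medians the second split was 572 higher and 205 lower. The cngc4 to akt1 count was 302 without cngc4 replicate 2, 350 without akt1 replicate 2, 720 without akt1 replicate 3 and 840 without cngc4 replicate 1. The cngc4 to cngc1 count was 123 without cngc4 replicate 2 and 248 without cngc1 replicate 3. Between cngc1 and akt1, 1 probe set was called, and 11 without akt1 replicate 1, 3 without ws2 replicate 3 and 2 without cngc1 replicate 3. The arrays of these 2 genotypes did not overlap for 14.9% of the probe sets tested, where chance gives 10%.

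Genes that set cngc4 apart from all 3 other genotypes numbered 282 higher and 126 lower probe sets. These 3 comparisons share the cngc4 arrays. Between the calls against ws2 and against akt1, 424 higher and 378 lower probe sets were shared, a number that the shared cngc4 arrays raise by an amount that was not estimated. The F test over the 3 mutants called 935 probe sets, of which 773 were also called in cngc4 against ws2. It called 153 without cngc4 replicate 2, 541 without cngc4 replicate 1, 579 without cngc4 replicate 3, 612 without ws2 replicate 1, 597 without ws2 replicate 2 and 614 without akt1 replicate 2.

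No probe set passed in more than 1 mutant against ws2; 1 did without akt1 replicate 1 and 1 without cngc1 replicate 2. With 0 probe sets called in akt1 and 1 in cngc1 this count could not exceed 1, so it says little about shared changes. AT3G05950 and AT5G66180 read higher on every array of the 3 mutants than on any ws2 array, and passed in cngc4 alone. Both were named from comparisons with these same ws2 arrays, and low readings there alone would give this pattern. How many probe sets show it by chance was not counted, so it is not evidence of a shared change. Across genes, which are not independent replicates, the fold changes of cngc1 and cngc4 had a correlation of 0.38 and a covariance of 0.0283, and simulated unchanged mutants against the same ws2 arrays gave 0.50 and 0.0178. For akt1 and cngc4 the covariance was 0.0177 against a simulated 0.0178, and for akt1 and cngc1 it was 0.0128 against 0.0177. The comparisons of cngc1 with ws2 and of cngc4 with akt1, which share no array, had a covariance of 0.0155 and a correlation of 0.21. Values for the other pairs that share no array follow. Their sign depends on which genotype of a comparison is named first, so it carries no meaning alone. The covariance was 0.0105 (correlation 0.13) for cngc4 with ws2 and cngc1 with akt1. It was 0.0050 (correlation 0.08) for akt1 with ws2 and cngc4 with cngc1. This last covariance follows by algebra from those of the other pairs that share no array, so it is not separate evidence.

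With all arrays, the share of genes called in cngc4 next to each targeted locus did not differ from the rest past the threshold. Of the 200 tested genes nearest to CNGC4 on both sides, 19 were called (9.5%), against 8.30% of the rest (Fisher's exact test, two-sided, p = 0.517). Near CNGC1 21 of 200 were called, 10.5% against 8.28% of the rest (Fisher's exact p = 0.245), and near AKT1 11 of 200 (Fisher's exact p = 0.155). CNGC1 and CNGC4 lie close together on the same chromosome, so their windows share genes and are not separate tests. Near AKT1 the share was lower than in the rest, 5.5% against 8.41%. Without ws2 replicate 2 or 3 it was also lower, with Fisher's exact p = 0.00725 and p = 0.00704. In akt1 and cngc1 the test is void, because 0 and 1 of the genes placed on the chromosomes were called.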

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

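Of the tests below, those on splits within pairs of genotypes, on a single outlying array and on a mislabelled array were chosen after the results had been seen. Tested directly, cngc4 differed from the other mutants, with 1310 probe sets against akt1 and 762 against cngc1, while 1 passed between cngc1 and akt1. That 1 call does not show cngc1 and akt1 to be alike. Between them 1651 probe sets had an unadjusted limma p under 0.05, where chance gives 737. The plastid-encoded genes differed between cngc4 and akt1 with camera adjusted p = 5.56e-24 at a preset correlation and adjusted p = 0.206 with an estimated correlation; all 62 had a positive log2 fold change, with a median of 0.73.

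The large count in cngc4 could come from whatever the repeat mark stands for, which the titles do not say (hybridization, labelling or growth), but the akt1 arrays and cngc4 replicates 2 and 3 carry no repeat mark, and 572 probe sets were still called between them, which argues against the mark as the whole cause. The highest actin 3-prime to 5-prime ratio in cngc4 was 1.94, below the 2.06 of an akt1 array, but for GAPDH cngc4 replicate 2 had the highest ratio of all arrays, just above the 1.24 of cngc1 replicate 1. The bound set in advance asked for both controls within the range of the other arrays; it was loosened after these values were seen and then put back, so RNA degradation stays undecided. Without cngc4 replicate 2, the array whose removal lowered the count most, 321 remained, all among the 1340 calls, so no single array is the whole cause. A genotype effect stays open as a hypothesis, as do a difference in growth or harvest between genotypes, which no label records, and a difference of accession, since the labels do not give the background of the cngc lines.

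Chance could be tested for the F test alone. Of 100 splits of the 12 arrays 1, the real one, gave as many as 935 probe sets, and the highest other gave 672. That argues against chance for the F test without excluding it. Each pair of genotypes has 10 splits, too few for a share under 0.05. The real value and the highest other split were 1340 and 1 for cngc4 against ws2 (1 split as large), 1310 and 3 for cngc4 against akt1 (1 split), 762 and 0 for cngc4 against cngc1 (1 split) and 1 and 0 for cngc1 against ws2 (1 split). They were 0 and 0 for akt1 against ws2 (10 splits). For cngc1 against akt1 they were 1 and 88 (2 splits): the split that sets akt1 replicate 1 with cngc1 replicates 1 and 2 called 88, which points to a structure of these arrays.

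Higher photosynthesis genes in cngc4 could come from shoot tissue in the root samples. The Calvin cycle genes RCA, PRK and SBPASE, which shoots express strongly, differed from the other nuclear photosynthesis genes by a median of 0.0574 on the log2 scale, with a standard error of 0.15. They were thus not lower than the rest, but 5 of 19 genes passed, short of the majority set in advance. Adjusted over the list alone, 10 of 19 passed. The folds were uneven, from 1.34 for LHCB4.1 to 0.36 for SBPASE with 2 genes negative. Shoot tissue and a change within roots therefore cannot be told apart. Few strong shoot transcripts are named here, which keeps this open.

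The lower AT1G27090 in cngc1 was carried by 3 of 3 cngc1 arrays, the highest at 27.8. No array of another genotype carried it, the lowest of these reading 119. The gene was named because it passed between these groups, so its separation cannot tell whether an array is mislabelled. The 10 tested genes on each side had a mean absolute moderated t at the 95.5th percentile of 10000 random windows, just past the 95th percentile set in advance, which a linked block of changed genes would give, although 0 of the 20 were called. A sequence difference at the probe set or a lesion of the gene in this line was not tested and stays open beside a regulatory change.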

How the results depend on the processing

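No named gene changed direction with a call, and AT1G27090 passed in all 26 alternatives of each of its 3 comparisons, with an adjusted p between 1.2e-06 and 5.31e-04 against ws2. The causes of the changes below were not tested. The array-left-out ranges were 321 to 1500 for cngc4 against ws2, 302 to 1548 against akt1, 123 to 873 against cngc1, 153 to 1238 for the F test, 0 to 1 for akt1, 1 to 3 for cngc1, 1 to 11 for cngc1 against akt1, and 0 to 1 for changes shared by mutants. Lists called ranged from 1 to 5 in akt1, 0 to 3 in cngc1 and 7 to 13 in cngc4, and the exact p of neighbours from 0.00704 to 0.805 at AKT1. Without a filter the counts were 813 (cngc4 against ws2), 797 (against akt1), 402 (against cngc1) and 442 (F test). Array weights gave 2364 for cngc4 against ws2, 1759 for the F test, 4 for cngc1 against akt1 and 1 for akt1. The repeat mark as covariate gave 714 for cngc4 against ws2 and 1 list in cngc1, which is neither of the lists described. Only the arrays without that mark, an alternative chosen after the data were seen, gave 15 (with 1 ws2 array), 572 and 424 for cngc4 against ws2, akt1 and cngc1, 162 for the F test, 5 lists in akt1 and 1 in cngc1, again neither of the lists described. Fits of the 2 groups alone gave 341 for cngc4 against cngc1. An unadjusted p with a 2-fold change gave 259, 261 and 226 for cngc4 against ws2, akt1 and cngc1, 4 for akt1, 21 for cngc1, 22 for cngc1 against akt1, and 5 changes shared by mutants. The 60th-percentile filter called 6 lists in akt1. An estimated correlation called 0 lists in each mutant; fry called 0 in akt1, 0 in cngc1 and 6 in cngc4. The replicate block gave 1273 for cngc4 against ws2, of which 1180 were among the 1340, with 1370 and 761 against akt1 and cngc1, and changed no other count by over 1.5 times; the numbers do not pair the samples. The F test has no fit of 2 groups, and the 2-fold threshold does not apply to lists, neighbours or the F test. Of 85 calls of named genes, 60 were lost with only the unmarked arrays, 44 without cngc4 replicate 2 and 37 under the 2-fold threshold.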

Other observations

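Single genes of amino acid and carbon metabolism that rose in cngc4 over ws2 are given here; they were chosen after their values were seen, and no test of these pathways as groups was made. IVD, isovaleryl-CoA dehydrogenase of leucine breakdown, had a log2 fold change of 1.62 (limma adjusted p = 9.48e-04), and ALDH6B2, which acts in valine breakdown, 0.68 (adjusted p = 0.0102). The aldehyde dehydrogenase ALDH7B4 read 1.34, formate dehydrogenase FDH 1.53 and pyruvate orthophosphate dikinase PPDK 1.44. The SnRK1 kinase subunit gene AKINBETA1 read 0.96, the linker histone gene HIS1-3 1.36 and the lipase gene SDP1, which breaks down storage oil, 0.56.

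Further single genes fell in cngc4, and no group was tested. The directional growth gene SKU5 read -0.98, the receptor kinase gene THE1, which senses cell wall state, -0.63, and the actin gene ACT11 -0.79, each past the threshold. These too were chosen after their values were seen.

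A hypothesis from this pattern is that leucine breakdown as a pathway may be raised in cngc4. ETFALPHA, ETFBETA, ETFQO and D2HGDH were taken in advance as electron transfer partners of leucine breakdown. Of these, D2HGDH encodes a dehydrogenase and not an electron carrier. The 4 genes, which had not been looked at, had log2 fold changes of 0.00, 0.39, 0.41 and 0.19. Their mean of 0.25 lay at the 93.2 percentile of 10000 random sets matched on signal, below the 95th percentile set in advance, and none of the 4 passed, so the extension to these genes was not borne out.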
